A study of Mus musculus with 8 samples.

How the data were processed

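DNA methylation was measured by enhanced reduced representation bisulfite sequencing, in which restriction fragments rich in CpG dinucleotides are sequenced after bisulfite has turned unmethylated cytosines into thymine. The cells were hematopoietic stem cells sorted from mouse bone marrow by their surface markers and not cultured. Per the labels, 4 mice carried a conditional Atg12 deletion (loxP-flanked Atg12 with the interferon-inducible Mx1-Cre) and 4 were controls. The series' design text describes the controls as mice with the same loxP-flanked alleles and no Cre, while the genotype label of each control reads wild type, so whether they carry loxP sites is open. Every library came from a separate mouse. The replicate numbers are mouse numbers that the groups do not share, so no pairing was used.

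The deposited tables list cytosines of CpGs on either strand, each table from a single mouse, with 2 kinds of value. The authors' coverage is a count of reads over each cytosine, with no listed cytosine under 10 reads for any mouse. The authors' methylation values are percentages of those reads that show C or T, per the file headers. Per the submitters' processing notes, CASAVA 1.8.2, Bismark and the mm10 build were used; filters, trimming and the treatment of duplicate reads are not given in the sources used here. The library protocol in the labels states a size selection changed for low amounts of DNA. Reads without molecular identifiers are not independent molecules, so the coverage overstates the number of DNA molecules behind a level.

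Methylated and unmethylated reads were recovered by multiplying coverage and percentage and rounding to whole reads. Both strands of a CpG were added. A CpG entered when every mouse had at least 10 reads, none lay above its own 99.9th percentile of coverage, and the CpG lay on chromosomes 1 to 19. This left 1077746 CpGs of the 5338121 listed for any mouse. Tests were run on CpGs, regions and gene ends with a mean level over the 8 mice from 5 to 95%, a filter that does not use the groups. Regions were non-overlapping 1 kb windows with at least 3 CpGs. Reads were summed over the CpGs of a region or gene end.

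The gene table was that of NCBI RefSeq for assembly GRCm38.p6, which is the mm10 build and gives each gene's start and end without strand or exons. Promoters could therefore not be placed by transcription start. In their place the end of each protein-coding gene with more listed CpGs within 1000 bp was used, called its gene end here, with the lower coordinate taken for 832 autosomal genes that had equal numbers at both ends. Of 20665 autosomal protein-coding genes, 13413 gene ends had at least 3 usable CpGs and 1897 were in the tested range of levels. Among these, 121 windows held the same reads as the window of another gene. Exons, introns and untranslated regions could not be told apart and are not reported.

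For each CpG, region and gene end, a logistic model of methylated and unmethylated reads on genotype was fitted across the 8 mice with quasi-binomial overdispersion. The overdispersion was moderated across features with squeezeVar of limma 3.58.1 in R 4.3.3 and not allowed under 1, and Benjamini-Hochberg adjustment was used at 0.05. Mean levels per mouse, over all autosomal CpGs, in 7 genomic contexts, on X and over each gene list, were compared by exact two-sided permutation tests over the 70 arrangements of 4 against 4, whose smallest p is 0.0286. Their 95% intervals were made by inverting the same test. CpG density was the number of CpGs listed for any mouse within the 500 bp around a CpG. The 14 gene lists were tested with camera of limma, using an estimated correlation, on log2 of methylated over unmethylated reads with 1 read added to each, for the 8 lists with at least 3 tested gene ends. Of the 483 list entries, 11 symbols had no protein-coding row in the gene table.

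The models were tested on simulated reads at the real features, with 200 changed features in each of 5 runs. The simulated spread of each feature was its own estimate from the 8 mice, before moderation. A difference of 20 percentage points was recovered for 0% of CpGs, 28.4% of regions and 69.2% of gene ends, and one of 40 points for 4% of CpGs, 72.4% of regions and 94% of gene ends. With nothing changed, the largest number of calls in any run was 0 for CpGs, 0 for regions and 1 for gene ends. In the same runs an unadjusted p under 0.05 was reached by 7.71% of the 238580 CpGs, 6.54% of the 39829 regions and 5.69% of the 1897 gene ends, slightly above the nominal 5%. Because the spread of each feature was estimated from few mice, these shares are not an exact chance level for the real data. For the gene lists, a shift of 2 on the log2 scale was recovered in 100% of the simulated tests and 0% of unshifted lists reached an unadjusted p under 0.05. Only this large shift was tried, on values with the genotype means removed, so the recovery of smaller shifts is not known.

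A coverage ratio was computed for each library as the median coverage of CpGs at 90% or more in every mouse over that of CpGs at 10% or less in every mouse. Only CpGs with 10 to 19 CpGs in the surrounding 500 bp were used, so that CpG density was alike. This measure, and the alternatives built on it, were chosen after seeing the data.

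The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Atg12, the 8 gene ends and 8 regions with the largest fall and likewise with the largest rise among those past the threshold whose groups do not overlap, and the 2 members of each list with the smallest p. Places left empty go to the smallest p in that direction, and predicted genes are passed over among gene ends. No gene end or region passed, so every such place was filled by its p. Of the list members that the rule names, 2 are not reported here.

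Alternatives covered the coverage limits, the sites and strands used, window sizes, the filter on levels, each mouse left out, chromosome 18 left out, a minimum difference, an unmoderated fit, edgeR 4.0.16's quasi-likelihood test, Fisher's exact test on pooled reads and limma on log2 ratios. Added after seeing the data were a trend in the moderation, limma on arcsine levels, the coverage ratio as a covariate, a fit without the pair of libraries of lowest ratio, and, for the lists, exact tests of list means and camera on all measured gene ends. Regions at an unadjusted p under 0.05 were placed on chromosomes for the same reason. Reads were held with the R package data.table, version 1.17.8. CpGs on X, Y and mitochondrial DNA stayed out of the tests of CpGs, regions and gene ends. X levels were compared by the exact permutation test above.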

Results

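Genome-scale DNA methylation was measured in purified hematopoietic stem cells, defined as lineage-negative, c-Kit+, Sca-1+, Flk2-, CD48-, CD150+ bone marrow cells, of 4 mice with conditional deletion of Atg12 and 4 control mice on a C57BL/6 background. Atg12 encodes a ubiquitin-like protein that is conjugated to Atg5 and is needed for autophagosome formation. Both groups received poly(I:C), which induces Mx1-Cre, at 4 weeks of age, and the cells were taken 2 to 3 months later. The question was whether the methylome of stem cells changes when this autophagy gene is lost. Each table listed between 2038266 cytosines (knockout 45) and 3366162 cytosines (knockout 25). Over the 1077746 autosomal CpGs covered in all 8 mice, median coverage ranged from 210 reads in knockout 28 to 290 reads in knockout 25.

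The libraries differed in how well methylated DNA was covered. The coverage ratio of always methylated to always unmethylated CpGs was 0.468 in knockout 25, 0.668 in knockout 28, 0.886 in knockout 45 and 0.61 in knockout 46, against 0.948 in control 1, 0.358 in control 34, 0.958 in control 36 and 0.961 in control 37. The genotype means were 0.658 ± 0.173 and 0.806 ± 0.299 (SD, n = 4 each; exact permutation p = 0.4). The same mice also differed by genotype in their sex chromosomes, as given with the X chromosome below.

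Mean autosomal CpG methylation of the stem cells did not differ detectably by genotype. It was 30.7% ± 0.269 in the knockouts and 30.8% ± 0.658 in the controls (SD, n = 4 each), a difference of -0.0815 percentage points with a 95% interval from -0.84 to 1.15 (exact permutation p = 0.83). CpGs within 1 kb of either end of a protein-coding gene, a wider set than the gene ends defined above, were at 4.64% ± 0.0818 in the knockouts and 4.64% ± 0.174 in the controls. Gene bodies were at 47.6% ± 0.372 and 47.7% ± 0.911, and intergenic CpGs at 65.9% ± 0.581 and 66.1% ± 1.43.

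Methylation was lower at denser CpGs in both genotypes. Sparse CpGs, with 1 to 9 CpGs in 500 bp, averaged 82% ± 0.606 in the knockouts and 82.2% ± 1.6 in the controls, those with 10 to 19 averaged 59.2% ± 0.611 and 59.4% ± 1.27, those with 20 to 39 averaged 7.33% ± 0.177 and 7.37% ± 0.297, and the densest, with 40 or more, 1.02% ± 0.0333 and 1.01% ± 0.055. None of the 7 contexts passed the threshold (exact permutation tests, smallest adjusted p = 0.967). The widest interval among them, that of the sparse CpGs, ran from -1.87 to 2.78 percentage points. Control 34 had the lowest mean of all 8 mice in each of the 7 contexts. Without it the difference in mean CpG methylation was -0.44 percentage points (exact permutation p = 0.0571), and with CpGs weighted by their coverage it was -2.08 percentage points (exact permutation p = 0.514).

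**Figure D1:**
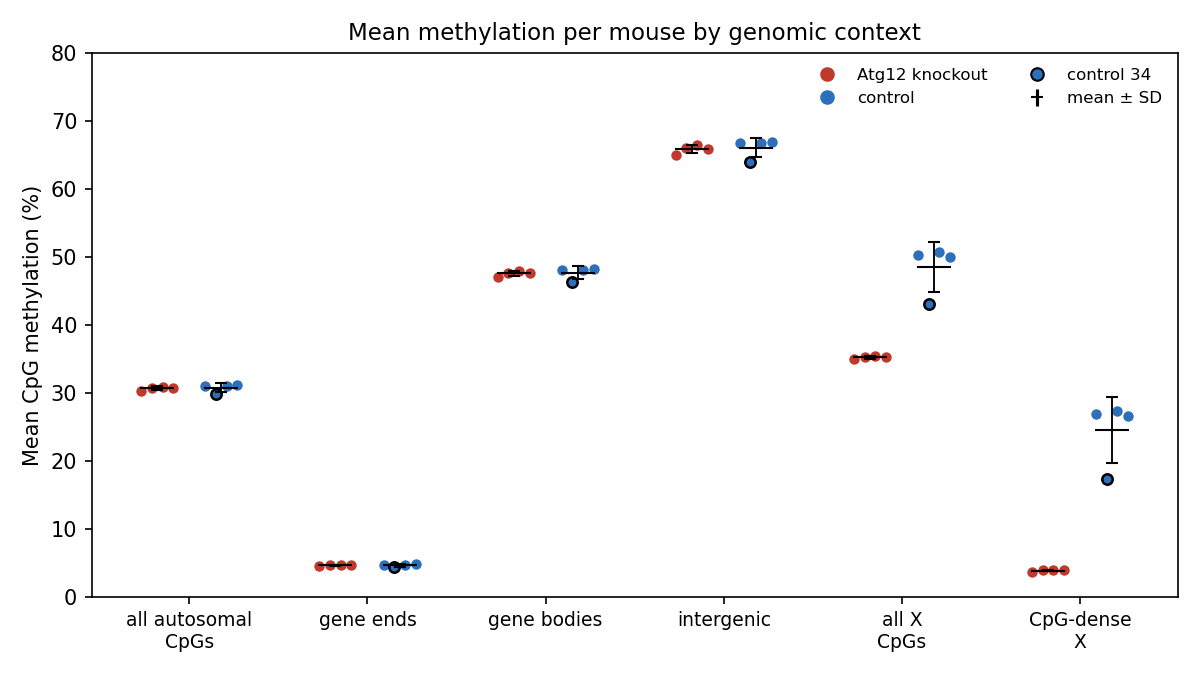
Mean CpG methylation in percent (vertical axis) of each mouse for 6 sets of CpGs (horizontal axis), with knockouts in red, controls in blue, control 34 ringed, and the mean ± SD of each group in black. Gene ends here are CpGs within 1 kb of either end of a protein-coding gene. The groups overlap on the autosomes, whereas on X the knockouts lie near 35.3% and the controls between 43.1% and 50.7%.

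X-chromosomal CpGs were less methylated in the knockouts, which also differed from the controls in Y content, as given below. Over 22016 CpGs the level was 35.3% ± 0.21 in the knockouts and 48.5% ± 3.63 in the controls (SD, n = 4 each), a difference of -13.3 percentage points with a 95% interval from -15.7 to -7.63 (exact permutation p = 0.0286, the smallest this design can give), lower in 4 of 4 knockouts. At CpG-dense X sites, with 20 or more CpGs in 500 bp, the level was 3.88% ± 0.0982 against 24.6% ± 4.81, while autosomal sites of that density were at 3.23% ± 0.0754 against 3.24% ± 0.138. Sparse X CpGs were at 84.3% ± 0.34 against 85.6% ± 1.53 (exact permutation p = 0.143). CpG-dense sites on the inactive X of female cells are known to be methylated.

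Y cytosines made up 8.52 ± 0.472 per 10000 listed cytosines in the knockouts and 1.45 ± 0.286 in the controls, and X cytosines 1.88% ± 0.0444 and 2.48% ± 0.0461 of those listed (SD, n = 4 each). The lowest knockout had 7.9 Y cytosines per 10000 and the highest control 1.83. The sex of the mice is not given in the labels. Genotype and Y content coincided in all 8 mice, so a difference by genotype and one between mice of high and low Y content cannot be told apart in any comparison here.

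Atg12 itself was unmethylated at its CpG-rich end in both genotypes. The gene lies on chromosome 18 from 46732417 to 46741724, and the 78 usable CpGs between 46740724 and 46742724 were at 0.23% ± 0.128 in the knockouts and 0.107% ± 0.0516 in the controls (SD, n = 4 each; exact permutation p = 0.143). Only 2 cytosines inside the gene, more than 1 kb from either end, were covered in all mice. Which part of the gene is deleted is not given in the sources used here, so whether these cytosines lie in it is not known. The genotype labels could therefore not be checked from these data.

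The 1 kb region with the smallest p of all 39829 tested, and the tested region closest to Atg12, lay 4417 bp away in the adjoining gene Cdo1, which encodes cysteine dioxygenase. It spans 46727001 to 46728000 on chromosome 18, near the end of Cdo1 at 46728502. Its 6 CpGs, all between 46727749 and 46727844, averaged 17.3% ± 6.72 in the knockouts and 1.92% ± 0.777 in the controls (SD, n = 4 each). Reads summed over these CpGs were 2237 to 3692 per mouse, and a read that spans several of them counts for each. The knockouts were at 9.91%, 13.2%, 23.2% and 22.7%, and the controls at 1.64%, 3.05%, 1.72% and 1.27%. The region did not pass (adjusted p = 0.132, moderated quasi-binomial model). Among the differentially methylated 1 kb regions it was called without knockout 25 (adjusted p = 0.0437) and without control 34 (adjusted p = 0.0355), and, in a fit chosen after seeing the data, without both (adjusted p = 0.0189), with adjusted p from 0.0189 to 0.678 over all its alternatives. The gene end of Cdo1 as a whole, 38 CpGs, was at 4.15% ± 1.31 and 0.822% ± 0.202 and too low to be tested.

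**Figure D2:**
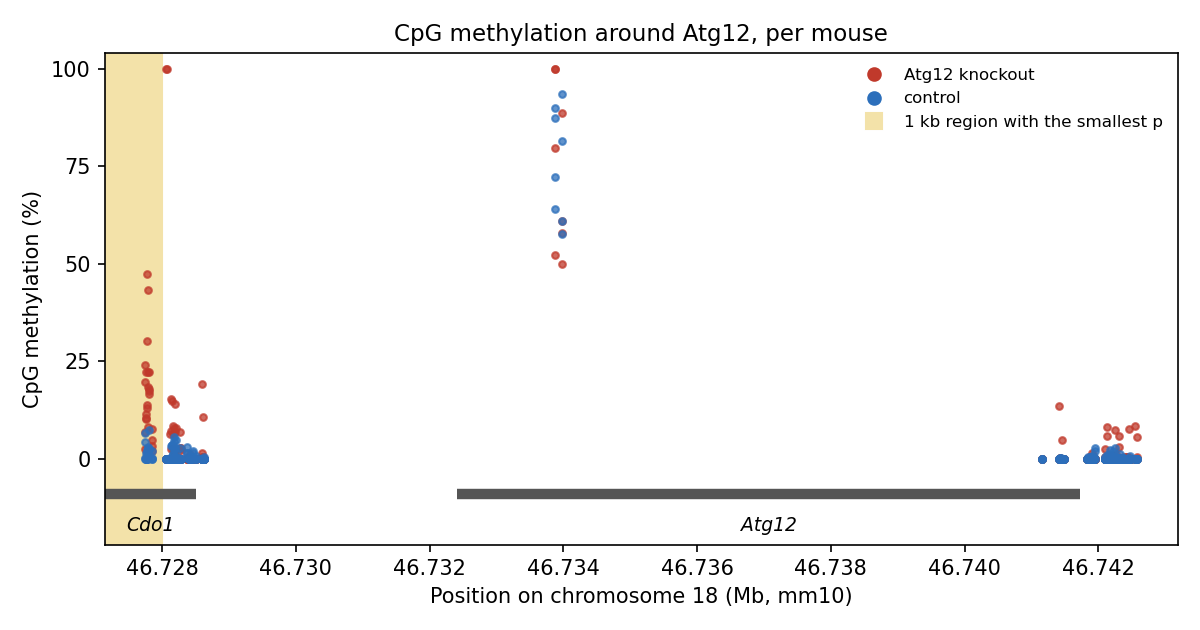
Methylation in percent (vertical axis) of the CpGs covered in all mice around Atg12, by position on chromosome 18 in Mb (mm10, horizontal axis), with 1 point per CpG and mouse, knockouts in red and controls in blue. Grey bars mark the genes, and shading marks the 1 kb region in Cdo1 whose mean is 17.3% in the knockouts and 1.92% in the controls, while the CpG-rich end of Atg12 is near 0 in both.

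At single CpGs, 1 of 238580 tested sites differed by genotype. It lies on chromosome 3 at 152092740, 1099 bp outside Gipc2, a gene for a PDZ domain protein, and fell from 71% ± 10.9 in the controls to 25.5% ± 15.1 in the knockouts (SD, n = 4 each; adjusted p = 0.00707, moderated quasi-binomial model). Knockout 45 at 47.2% and control 34 at 56.5% came closest to each other. Coverage there was 531 to 1017 reads per mouse. All 13 other CpGs within 250 bp were lower on average in the knockouts, but the 1 kb region that holds them differed by -34.7 percentage points and did not pass (adjusted p = 0.586). The site is outside the rule for named genes and was named after its values were seen. Other tests counted 0 differentially methylated CpGs, with 6969 at an unadjusted p under 0.05 by edgeR, 12380 by limma on log2 ratios and 15952 by the unmoderated model. An unadjusted p under 0.05 was reached by 15228 CpGs, 6.38%, of which 9472 were lower and 5756 higher in the knockouts, against 7.71% in simulated data with no change. That simulated share is not an exact chance level. The number of called CpGs was 110 without knockout 45, 11 without control 34, 4 without knockout 46, 2 without knockout 28 or control 37, and 0 without knockout 25.

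There were 0 differentially methylated 1 kb regions among the 39829 tested (moderated quasi-binomial model). At an unadjusted p under 0.05 there were 2591 regions, 6.51%, of which 1758 were lower and 833 higher in the knockouts. Simulated data with no change gave 6.54%, which is not an exact chance level here either. Other splits of the same mice into equal groups, given below, ran from 1412 to 4680 such regions. Most had fewer than genotype, and those with more had 2593, 3370, 3518 and 4680. The group values did not overlap in 1384 regions, 3.47%, where chance gives 2.86%. Differences were under 10 percentage points in 92.5% of regions. edgeR's quasi-likelihood test also called 0 regions, with 1511 at an unadjusted p under 0.05, as did limma on log2 ratios, with 1909. Without control 34, 25 regions passed, 24 of them lower in the knockouts, and without knockout 45, 6 passed. Without both knockout 25 and control 34, the libraries of lowest coverage ratio, 3 passed.

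In each of the 8 regions with the smallest p on the lower side, none of which passed, every knockout was below every control. On chromosome 14 at 64067001 to 64068000, 7435 bp from Prss55, the level was 11.7% ± 2.83 in the knockouts and 43.2% ± 7.64 in the controls. In Bri3, on chromosome 5 at 144252001 to 144253000, it was 3.93% ± 2.99 and 36% ± 5.96. At 74126001 to 74127000 on chromosome 5, with no gene within 50000 bp, it was 14% ± 4.73 and 46.5% ± 16.8, with knockout 25 at 18% and control 34 at 21.8%. In P2rx7, which encodes an ATP-gated ion channel, at 122678001 to 122679000 on the same chromosome, it was 3.31% ± 3.03 and 19.8% ± 6.39. Each of these first 4 passed when control 34 was left out. The others were 5739 bp from Gm32719 (chromosome 12, 20234001 to 20235000; 61.7% and 82.8%), in Adgrb2 (chromosome 4, 130007001 to 130008000; 58.9% and 76.1%), in Tmem198 (chromosome 1, 75484001 to 75485000; 72.5% and 85%) and 4423 bp from Lta (chromosome 17, 35210001 to 35211000; 32.8% and 57.2%). Adjusted p ran from 0.132 to 0.427 over these 8. The regions near Gm32719 and in Tmem198 passed without knockout 45, each at an adjusted p of 0.0489.

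On the higher side the region in Cdo1 came first, and the other 7 likewise did not pass. At 25220001 to 25221000 on chromosome 16, with no gene within 50000 bp, the knockouts were at 93.6% ± 4.76 and the controls at 50.8% ± 11.6. At 21119001 to 21120000 on chromosome 7, 13211 bp from Vmn1r122, they were at 76.3% ± 16.2 and 44.5% ± 7.37. In Cbfa2t3, which encodes a transcriptional corepressor of the ETO family expressed in blood stem cells, at 122674001 to 122675000 on chromosome 8, they were at 52.8% ± 5.47 and 37.4% ± 5.27. The remaining regions were in Arhgef18 (chromosome 8, 3392001 to 3393000; 10.4% and 2.88%), 35708 bp from Obox7 (chromosome 7, 14623001 to 14624000; 9.64% and 5.18%), in Pcbp4 (chromosome 9, 106455001 to 106456000; 72.1% and 49.4%) and in Gal3st3 (chromosome 19, 5298001 to 5299000; 32.3% and 21.9%). Adjusted p ran from 0.132 to 0.586.

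None of the 1897 tested gene ends passed (smallest adjusted p = 0.643, moderated quasi-binomial model), and 88.7% of the 13413 measured gene ends of these stem cells were under 20% methylated. At an unadjusted p under 0.05 there were 114 gene ends, 77 lower and 37 higher in the knockouts, 6.01% against 5.69% in simulated data with no change. That simulated share is no exact chance level either. edgeR called 0 gene ends, with 79 at an unadjusted p under 0.05, and limma on log2 ratios 0, with 87. The count stayed at 0 with each mouse left out and without both libraries of lowest coverage ratio.

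The gene ends with the smallest p on the lower side were Tspoap1 (25.1% ± 5 in the knockouts and 40.4% ± 4.39 in the controls), Lmod1 (70.7% ± 1.96 and 78.3% ± 1.2), Iqcn (26% ± 3.88 and 47.3% ± 12.7), Lrrc3c (56.9% ± 5.48 and 71% ± 4.27), Csf2rb (12.3% ± 2.62 and 22.7% ± 5.64), Irf4 (10.4% ± 1.11 and 16.6% ± 2.55), Slc26a10 (14.3% ± 5.07 and 26.3% ± 4.13) and Ldb3 (61.5% ± 8.96 and 75.8% ± 9.9). Csf2rb encodes the shared signalling subunit of the IL-3, IL-5 and GM-CSF receptors, and Irf4 a transcription factor of lymphoid and myeloid cells. The window of Csf2rb lies on chromosome 15 at 78324800 to 78326800 and holds 4 CpGs, and that of Irf4 lies on chromosome 13 at 30748233 to 30750233 and holds 14. All but Ldb3 had non-overlapping groups, and adjusted p ran from 0.643 to 0.682.

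On the higher side were Ephb3 (11.9% ± 0.71 and 9.14% ± 0.989), Gal3st3 (32.3% ± 3.69 and 21.9% ± 2.76), Cers1 with Gdf1 (both 94.3% ± 0.329 and 90.4% ± 2.31), Mxra7 (9.41% ± 0.541 and 7.46% ± 0.622), Cacng6 (9.16% ± 1.77 and 6.32% ± 0.463), Ankrd33 (83.4% ± 4.11 and 73.9% ± 1.35) and Tmem150b (37.3% ± 7.32 and 25.7% ± 4.61). Ephb3 encodes an ephrin receptor and Cers1 a ceramide synthase. The windows of Cers1 and Gdf1 hold the same CpGs, so they count as 1 measurement. Their adjusted p ran from 0.643 to 0.757, and none passed.

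Most measured genes of the autophagy machinery and of energy metabolism had gene ends under 5% methylated, 37 of 38 for autophagy, 47 of 49 for oxidative phosphorylation, 36 of 37 for the TCA cycle list and 19 of 24 for glycolysis, as did 11148 of all 13413 measured gene ends. The 38 measured autophagy genes averaged 2.1% ± 0.587 in the knockouts and 1.84% ± 0.917 in the controls. The 49 measured genes of oxidative phosphorylation averaged 1.63% ± 0.267 and 1.59% ± 0.209, and the 37 of the TCA cycle, fatty acid oxidation and one-carbon metabolism 2.8% ± 0.123 and 2.79% ± 0.324. The 24 glycolysis genes averaged 12.4% ± 0.769 and 12.9% ± 0.328 (SD, n = 4 each throughout). No member of these lists passed over all gene ends or adjusted over the list alone. Atg4c, which encodes a protease that processes Atg8 proteins and is the only tested autophagy gene, was at 70.9% ± 23.7 and 61.1% ± 34.2, with 9.96% in control 34. Its window lies at the upper coordinate of the gene. As strand is not given, whether the window of this or another named gene lies at its promoter is not known. Ndufs6 of complex I was at 11.3% ± 10.9 and 12.9% ± 9.66, Aldoa at 8.01% ± 3.36 and 5.67% ± 1.64, Pfkfb4 at 75.7% ± 19 and 91.3% ± 10.2, and Shmt2 at 89.9% ± 4.72 and 89.4% ± 9.7. Control 34, the library of lowest coverage ratio, was the lowest of the 8 mice for Atg4c and Shmt2, whose differences turned in direction without it, to -7.32 and -4.34 percentage points.

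The myeloid list had the smallest p of the 14 list means, a test added after seeing the data. Its 13 measured members averaged 35% ± 0.406 in the knockouts and 37.1% ± 1.01 in the controls, lower in 4 of 4 knockouts (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.4 over the 14 lists). Of its 6 tested members, 5 were lower and 1 higher, 0 passed over all gene ends, and 1, Csf2rb, passed adjusted over the list alone (adjusted p = 0.0265). Ctsg, which encodes the granule protease cathepsin G, was at 88.2% ± 3.71 and 95.3% ± 4.02. camera gave an adjusted p = 0.292 with an estimated correlation. Leaving out any of the 4 knockouts moved the exact permutation p of the list mean to between 0.0571 and 0.114, a coverage minimum of 20 reads moved it to 0.143, and without knockout 25 and control 34 it was 0.1, the smallest that 3 mice against 3 can give. With each mouse left out the difference ran from -2.53 to -1.82 percentage points. With 3 knockouts against 4 controls the two-sided test also counts opposite arrangements, so part of the rise in p can come from the unequal groups.

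Stem cell and other lineage lists did not differ past the threshold. The 24 measured genes of stem cell identity and self-renewal averaged 3.12% ± 0.327 and 4.31% ± 1.51, with 21 under 5% (exact permutation p = 0.171, and 0.0286 without control 34, before adjustment), and the 19 lymphoid genes 25.6% ± 0.692 and 26.2% ± 0.418. The 13 genes of the megakaryocyte and erythroid list averaged 17.6% ± 1.22 and 18.1% ± 1.81, and the 9 of bone marrow stroma and endothelium, cells that the sorting gate would exclude, 2.22% ± 0.862 and 2.37% ± 0.366 (SD, n = 4 each throughout). No tested member passed over all gene ends or adjusted over the list alone. Cdkn1c, an imprinted cell cycle inhibitor that keeps stem cells quiescent, was at 27.8% ± 4.55 and 32% ± 3.11, and Ndn at 10.4% ± 11.7 and 26.2% ± 20.3. Slc4a1, the erythroid anion exchanger, was at 22.2% ± 13.7 and 31.8% ± 16.1, Treml1 at 76.8% ± 3.65 and 76.5% ± 3.6, Pdgfrb at 5.62% ± 5.39 and 7.96% ± 1.62, and Sp7 at 8.2% ± 1.59 and 8.32% ± 2.19.

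The level of imprinted genes went with the coverage ratio of the library. Their 30 measured gene ends averaged 21.9% ± 2.8 in the knockouts and 23.9% ± 4.81 in the controls (SD, n = 4 each; exact permutation p = 0.514), and the difference ran from -4.33 percentage points without control 34 (exact permutation p = 0.0571) to -0.57 without control 37. For the 14 with mean levels from 20 to 70%, the mean was 25.3% in knockout 25, 34.6% in knockout 28, 39.2% in knockout 45 and 30.5% in knockout 46, against 41% in control 1, 22.8% in control 34, 37.2% in control 36 and 40.2% in control 37. Across the 8 mice this mean went with the coverage ratio (Pearson r = 0.97, exact permutation p = 0.000273, adjusted p = 0.000818; Spearman rho = 0.881, exact permutation p = 0.00724, adjusted p = 0.0109; 3 relations were computed), and r was 0.906 without control 34 and knockout 25. The mean of 1 kb regions at 20 to 80% also went with the ratio (Pearson r = 0.961, exact permutation p = 0.000744; Spearman rho = 0.881, exact permutation p = 0.00724), with r = 0.949 without those mice. With the mean of each genotype removed, a test added after seeing the data, Pearson r was 0.975 for imprinted genes (n = 8, exact permutation within genotypes p = 0.00868, adjusted p = 0.0208) and 0.984 for the regions (exact permutation p = 0.0208, adjusted p = 0.0208), and 0.86 and 0.872 without those 2 mice, while Spearman rho, on ranks within each genotype, was 0.7 (exact permutation p = 0.111, adjusted p = 0.295) and 0.5 (exact permutation p = 0.295, adjusted p = 0.295). Of the named members, Nap1l5 was at 50.9% ± 4.46 in the knockouts and 44.8% ± 3.27 in the controls and Sgce at 18.4% ± 12.6 and 33.1% ± 14.4. No member passed.

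**Figure D3:**
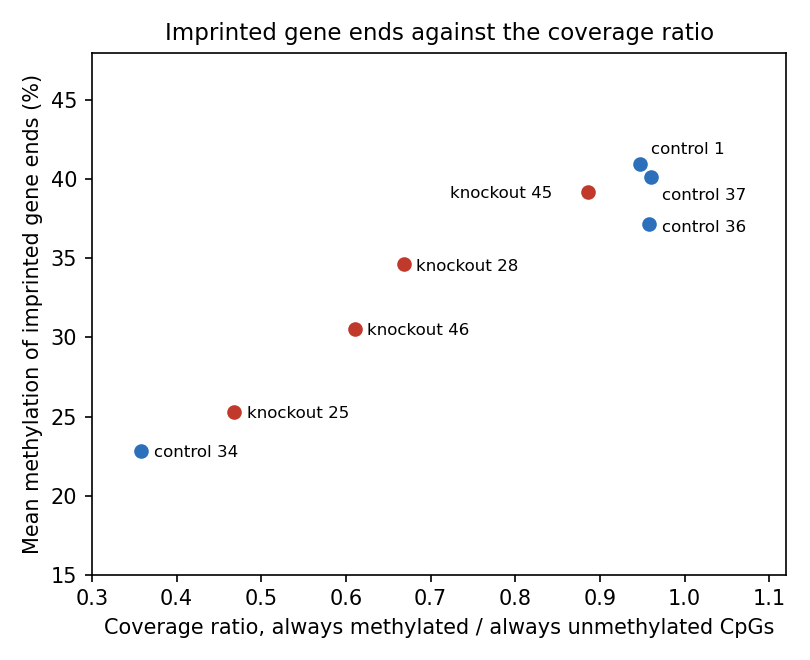
Mean methylation in percent of the 14 imprinted gene ends (vertical axis) against the coverage ratio of always methylated to always unmethylated CpGs (horizontal axis, no unit), with 1 labelled point per mouse, knockouts in red and controls in blue. Control 34, with a ratio of 0.358 and a level of 22.8%, lies at the low end beside knockout 25, and knockout 45 lies beside the other controls.

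Hox, germline, interferon and chromatin genes did not differ past the threshold. The 37 measured Hox genes averaged 8.31% ± 1.52 in the knockouts and 7.42% ± 1.25 in the controls. Among them the neighbouring Hoxa5 (47.8% ± 12.8 and 35% ± 9.85) and Hoxa6 (47.7% ± 12.8 and 35% ± 9.88) had the smallest p and share most of their CpGs. The 21 germline genes, usually silenced by methylation in somatic cells, averaged 79.5% ± 0.802 and 79.4% ± 2.94 (without control 34 the difference was -1.33 percentage points, exact permutation p = 0.0286 before adjustment), with Ddx4 at 85% ± 3.83 and 89.3% ± 2.08 and Tdrd9 at 92.5% ± 2.06 and 95.5% ± 1.02. The 21 interferon response genes, of interest because poly(I:C) induces interferon, averaged 7.86% ± 0.352 and 8.44% ± 0.61, with Oas2 at 17.8% ± 12.1 and 27.8% ± 3.45 and Trim25 at 3.23% ± 1.47 and 7.37% ± 5.83. The 32 DNA methylation and chromatin regulators averaged 4.69% ± 0.657 and 4.7% ± 0.81, with Dnmt3l at 85.3% ± 10.4 and 84.5% ± 10.1 and Kdm6b at 53.2% ± 12.8 and 52% ± 17.3 (SD, n = 4 each throughout). No member passed over all gene ends or adjusted over the list alone. Control 34, of the lowest coverage ratio, had the lowest mean of the 8 mice for the Hox, imprinted, chromatin, germline and autophagy lists. It was also the lowest for the stem cell, megakaryocyte and erythroid, oxidative phosphorylation and TCA cycle lists.

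None of the 8 lists with at least 3 tested gene ends passed camera with an estimated correlation (smallest adjusted p = 0.292, for both the myeloid and the interferon list, each on the lower side). With the preset correlation of 0.01 the smallest adjusted p was 0.137, and with fry, which tests whether a list's gene ends move on balance in 1 direction, it was 0.105 for the myeloid list. None of the 14 list means passed the exact permutation tests (smallest adjusted p = 0.4).

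Since no region passed, there were no called regions to place on chromosomes. Regions at an unadjusted p under 0.05 made up between 5.59% (chromosome 10) and 7.75% (chromosome 19) of those tested on each of the 19 autosomes, and no chromosome stood out (Fisher's exact test, smallest adjusted p = 0.604). On chromosome 18 they were 78 of 1213, 6.43%, and within 10 Mb of Atg12 they were 21 of 283, 7.42% (Fisher's exact test, p = 0.544).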

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

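All tests of explanations in this part were chosen after the result was seen. Chance alone puts about 1 in 20 groups of 4 past the outlier limit, 9 of the 180 groups tested, and 21 were found. Many of these groups share CpGs and all share the same mice, so they are not independent and the excess cannot be weighed as such. Of the 21 outliers, 19 were control 34.

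Control 34 stood apart from the other controls in autosomal methylation. Its mean was 29.8%, where the other controls were at 31.1%. In gene bodies it was at 46.3%, in intergenic DNA at 63.9%, at sparse CpGs with 1 to 9 in 500 bp at 79.8%, at 10 to 19 CpGs at 57.5% and at 20 to 39 CpGs at 6.93%. Regions of 1 kb with mean levels from 20 to 80% were at 50.6% in this mouse and between 59.6% and 59.8% in the other controls. Among the lists it lay past the outlier limit for autophagy genes (0.476%), the TCA cycle, fatty acid oxidation and one-carbon list (2.31%), imprinted genes (16.7%) and Hox genes (5.56%), and among named gene ends for Atg4c (9.96%), Shmt2 (75%) and Kdm6b (26.1%). Its coverage ratio was 0.358, against 0.948 to 0.961 in the other controls, and its mitochondrial over autosomal median coverage was 1.6, against 0.586 to 0.69. The region in Tmem198 was at 88% in control 1, against 83.6% to 84.3% in the other controls.

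Setting knockouts 25, 28 and 46 with control 34 against knockout 45 with the other controls called 682 CpGs, 282 regions and 53 gene ends, where genotype called 1, 0 and 0, which points to a structure of the samples. Sex is argued against, since control 34 listed 1.15 Y cytosines per 10000, as few as the other controls. A lower recovery of methylated DNA in 4 libraries is a candidate explanation, since those mice had the 4 lowest coverage ratios and the ratio went with the level of imprinted gene ends (r = 0.97). An exchange of the labels of knockout 45 and control 34 stays open, because only 2 cytosines inside Atg12 were covered in all mice and the labels give no sex, and no biological explanation other than sex was tested. Other values ran with the labels: knockout 45 and control 34 had 8.46 and 1.15 Y cytosines per 10000, 3.95% and 17.4% at CpG-dense X sites, and 23.2% and 3.05% in the Cdo1 region.

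X methylation differed more between the genotypes than any autosomal context mean. CpG-dense X sites were also at 17.4% in control 34, against 26.5% to 27.4% in the other controls, all X CpGs at 43.1% and sparse X CpGs at 83.3%, and knockout 25 was at 3.73% at dense X sites, against 3.91% to 3.95% in the other knockouts. Y cytosines, which lie outside the autosomal comparisons, averaged 8.52 per 10000 in the knockouts against 1.15 to 1.83 in the controls. A sex imbalance, male knockouts against female controls, may account for the X difference, since the lowest knockout had 4.32 times the Y cytosines of the highest control. X cytosines likewise made up 1.88% of those listed in the knockouts and 2.48% in the controls. CpG-dense X sites in the knockouts, at 3.88%, were near autosomal sites of that density, at 3.23%. The tables argue against a general loss at CpG-dense sites. Autosomal ones with mean levels from 5 to 95%, at 32.9% in the controls, differed by -0.124 percentage points (95% interval -3.9 to 5.18). X sites so chosen differed by -23.8 (-26.9 to -15.6). They were at 2.85% in the knockouts and 26.6% in the controls, so they can enter through the controls alone, which can enlarge their difference. Without that choice CpG-dense X sites differed by -20.7 percentage points. The tables also argue against low recovery of methylated DNA, since knockout 45, of high coverage ratio, was at 3.95% at CpG-dense X sites. An effect of genotype on X beyond that of sex stays open, as no control had high Y content and no knockout low Y content.

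The third pattern is the region in Cdo1, 4417 bp from Atg12, whose p was the smallest of 39829 although its adjusted p of 0.132 missed the threshold. Low recovery of methylated DNA is argued against, because knockout 45, whose coverage ratio was near that of 3 controls, was at 23.2%, against 1.27% to 1.72% in those. DNA of another strain that came along with the floxed allele, which would set the groups apart only if the controls lack that allele, as their label but not the design text has it, cannot be told apart from the genotype, since regions within 10 Mb were not detectably enriched in small p values (Fisher's exact test, p = 0.544) but a short block could act on this region alone. Sex cannot be told apart either, as 0 of the controls had as many Y cytosines as a knockout. A local change beside the recombined Atg12 allele is a hypothesis that these data leave open and do not test.

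Of the 35 splits of the 8 mice into 4 and 4, 10 called at least as many CpGs as the 1 of the real split, with 682 in the highest of the others, so chance could not be excluded for that count. For regions, gene ends and gene lists by camera the real count was 0, which 35 of 35 splits reach whatever the data hold, so the splits decide nothing on these counts. The highest of the others were 282 regions, 53 gene ends and 0 lists. Regions at an unadjusted p under 0.05 numbered 2591 by genotype, and the higher counts of other splits were 2593, 3370, 3518 and 4680.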

How the results depend on the processing

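Of the alternatives below, trend moderation, arcsine levels, the coverage ratio covariate, the fit without the pair of libraries of lowest coverage ratio (knockout 25 and control 34), the exact tests of list means, camera on all measured gene ends and the mice left out for X were chosen after seeing the data. Gene ends called 0 and lists and contexts called 0 under every alternative but those given here. Without an upper coverage limit there were 25 differentially methylated CpGs. With X included, 7394 CpGs, 690 differentially methylated 1 kb regions and 367 gene ends passed, with 7229 of those CpGs and 672 of those regions lower in the knockouts. Fisher's test on pooled reads, which ignores the spread between mice, called 153733 CpGs, 27118 regions and 1386 gene ends. The called CpG was lost, giving 0, with strands apart, without moderation, without the filter on levels, and with edgeR, limma on log2 ratios (centred or not), on arcsine levels or with the covariate. Leaving out each mouse gave 0 to 110 CpGs (110 without knockout 45, 11 without control 34, 4 without knockout 46, 2 without knockout 28 or control 37, and 0 without knockout 25), 0 to 25 regions (25 without control 34, 6 without knockout 45, 1 without knockout 25), and for X a difference of -14.8 to -12.6 percentage points. Without the pair of libraries, 3 CpGs and 3 regions passed. The cause was not tested.

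Weighted by coverage, the mean difference was -2.08 percentage points (exact permutation p = 0.514). Some differences changed sign. The mean difference was 0.109 percentage points with at least 3 mice of each group and -0.44 to 0.0473 with each mouse left out. With at least 3 mice of each group, gene bodies were at 0.153, CpGs of density 10 to 19 at 0.164 and the mean methylation, 20 to 39 CpGs in 500 bp, at 0.0304. With each mouse left out, CpGs within 1 kb of either end of a gene ran from -0.0918 to 0.0439, gene bodies from -0.61 to 0.04998, intergenic CpGs from -0.952 to 0.0627, and the 4 density classes from -1.03 to 0.0753, -0.829 to 0.0998, -0.19 to 0.0355 and -0.0152 to 0.0296. Without the pair of libraries, mean methylation, within 1 kb of a gene end (either end), was at -0.0522 and mean methylation, 40 or more CpGs in 500 bp, at -0.00382. Among list means, at 20 reads glycolysis was at 0.104 and chromatin regulators at 0.253. With each mouse left out, autophagy ran from -0.203 to 0.524, oxidative phosphorylation from -0.105 to 0.0966, the TCA list from -0.154 to 0.0793, chromatin regulators from -0.389 to 0.236, germline genes from -1.33 to 0.869 and stroma from -0.563 to 0.532, and without a change of sign stem cell genes from -1.88 to -0.272, lymphoid from -0.825 to -0.358, megakaryocyte and erythroid from -1.67 to -0.0632, glycolysis from -1.09 to -0.274, interferon from -1.28 to -0.163, imprinted genes from -4.33 to -0.57 and Hox from 0.217 to 1.34. Without the pair, autophagy was at -0.242, the mean level of list, oxidative phosphorylation, at -0.0355, the TCA list at -0.181 and germline genes at -1.41.

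Of 516 values of the 40 named gene ends, 493 kept direction and side of the threshold and 23 changed sign, and of 207 values of the 16 named regions, 196 did, 10 passed and 1 changed sign, that near Gm32719 with strands apart (7.83). Treml1 was at -1.71 with strands apart. With each mouse left out Atg4c ran from -7.32 to 20.7, Ndn from -24.6 to 0.968, Treml1 from -1.38 to 1.95, Ndufs6 from -6.75 to 2.31, Shmt2 from -4.34 to 2.66, Dnmt3l from -4.05 to 4.76, Kdm6b from -7.47 to 6.8 and Sp7 from -0.962 to 0.565. Without the pair, Atg4c was at -8.95, gene end Treml1 at -0.631, Shmt2 at -4.57 and gene end Kdm6b at -1.84. With 3 mice against 3, no exact test can go below 0.1. The variance between mice was 17.2 times the binomial variance of the reads at the median CpG, and how much of this comes from few sampled molecules was not tested.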

Other observations

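Chosen after seeing the data, the ratio of mitochondrial to autosomal median coverage was 2.27 in knockout 25, 1.72 in knockout 28, 0.571 in knockout 45 and 1.22 in knockout 46, and 0.626 in control 1, 1.6 in control 34, 0.586 in control 36 and 0.69 in control 37. It went against the coverage ratio of methylated to unmethylated CpGs (Pearson r = -0.871, exact permutation p = 0.00647; Spearman rho = -0.667, exact permutation p = 0.0831), with r = -0.867 without control 34 and knockout 25. Genotype means overlapped (1.44 ± 0.722 and 0.877 ± 0.487, n = 4 each; exact permutation p = 0.286). Part of the relation to the coverage ratio may be built in, since autosomal coverage includes methylated CpGs. Over unmethylated autosomal cytosines the mitochondrial ratio was 1.75, 1.44, 0.495 and 0.982 in knockouts 25, 28, 45 and 46. In controls 1, 34, 36 and 37 it was 0.573, 1.2, 0.518 and 0.608. The relation of this version to the coverage ratio was not tested.

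Mitochondrial cytosines were listed at an unweighted mean of 0.0327% to 0.151% methylation per mouse. With reads pooled over cytosines the level was 0.156% to 0.438%.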
